A study of Homo sapiens with 2 samples.

How the data were processed

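Poly(A) RNA of untreated cells was measured in 2 replicate libraries of 1 cell line, and each library came with a gene table and a transcript table. Per the labels' protocols, cells were grown at 37 °C and 5% CO2 in McCoy's 5A medium with 10% fetal bovine serum and geneticin at 500 µg/mL, RNA was taken with a column kit, and libraries were made with a directional kit after poly(A) bead capture. Per the submitters' processing notes, the tools were Trimmomatic 0.32, FastQC 0.11.2, TopHat2 2.0.13, Bowtie2 2.2.3 and Cufflinks 2.2.1, and the genome build was GRCh38. Settings and the annotation release are not given in the sources used here. Whether strand was used in quantification is also not given in the sources used here, so reads of overlapping genes on opposite strands may not have been told apart.

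The authors deposited FPKM (fragments per kilobase of transcript, scaled to the number of mapped fragments) with lower and upper confidence bounds and a status for each gene and transcript, per the file headers. The deposited transcript tables also hold an estimated depth of read coverage per transcript, per the file headers. Identifiers in the files show that Cufflinks assembled transcripts beside a reference annotation. Replicate 1 had 56294 gene entries and replicate 2 had 66625. Each library was assembled on its own, so identifiers made by the assembly cannot be matched between libraries and were not compared one by one.

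Most gene entries carried no symbol. Symbols were found from the RefSeq accession of each reference transcript in an NCBI gene table (GRCh38.p14 names) or, failing that, in the GENCODE 29 cross-references, and otherwise from the gene name that the files pair with it. Of the reference transcripts, 46564 were named by accession, 21269 by the files and 27547 had no name of their own. Gene names that a spreadsheet had turned into dates, 11 in replicate 1 and 12 in replicate 2, were recovered by accession where one was given. A gene's FPKM is the deposited value of its locus, which includes transcripts assembled there. Where a locus held several symbols, which was so for 777 symbols in either library, the FPKM of the gene's own reference transcripts were summed and no bound was given, and assembled transcripts of such loci were left out. Loci that share a symbol were summed. Genes with a failed status in either library (44) were left out, and 29098 genes were left. Locus starts count from 0 in the files, and 1 was added to each start printed. Of 24078 genes compared with the NCBI gene table, 9392 had the same start after that step and 247 before it.

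Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used. A gene counted as detected at FPKM 1 or more. Ratios between the libraries are log2 of (FPKM + 1) in replicate 2 over replicate 1, among genes at FPKM 1 or more in at least 1 library; on this scale the ratio of genes with low FPKM is understated. Genes counted as differing when the absolute log2 ratio was 1 or more and the deposited confidence bounds did not overlap. Gene lists (31) were fixed before the data were examined. The median ratio of a list with 5 or more such members was set against 10000 random lists of the same size, drawn with replacement within 20 bins of mean expression. The central 95% of the random medians was the stated mark. These are descriptions of 2 libraries of 1 group, and no p-value was computed between the libraries. Further lists (6) were written after the files were at hand and before their values were seen.

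The counting rule and the list percentile were tested on simulated data: the 2 libraries were simulated for 11857 genes with 50 genes changed by each fold size. All 50 genes changed 4-fold upward were recovered, as were all 50 raised 3-fold and all 50 with a fold of 0.25, and 49 of the 50 lowered 3-fold. In that simulation 0 unchanged genes were counted, a list of 20 genes raised by 0.4 (log2) lay at percentile 100, and 0 of 40 unshifted lists lay outside the central 95%. The simulated spread between libraries was set smaller than the real one (SD of the log2 ratio 0.56). It had bounds of a fixed relative width and no trend with length or GC content. The simulation thus checks that the code works, and cannot show how often the rules err on the real libraries.

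The depth per library is known only in relative terms. Coverage divided by FPKM had a median of 5.78 in replicate 1 and 5.57 in replicate 2 over transcripts of at least 100 bases. With equal read lengths, replicate 1 was thus 1.04 times as deep as replicate 2. The confidence bounds cover the estimation within a library, not the spread between libraries. Values are given as mean ± SD with n = 2. Where a library lists a gene at 0, both values are given instead, since genes that every cell uses were also listed at 0, and a listed 0 can be a failed estimate.

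Genes named in the text were chosen by a rule fixed before the data were examined: the 15 genes of highest mean FPKM; in each list, members under FPKM 1 in both libraries and the 4 of highest mean FPKM, and every member of the lists for CDK inhibitors, telomere maintenance, end joining, osteoblast markers, the reporter and the G1 machinery; the 10 differing genes of largest ratio in each direction at mean FPKM of 5 or more; and for transcripts 12 genes. Names chosen otherwise are marked. Alternatives changed the FPKM minimum, the pseudocount, the filter, the scaling, the choice among entries of 1 symbol, the status filter and the library used. Alternatives that used reference transcripts only, left out genes at 0 or overlapping genes, or removed a trend with length and GC content were chosen after seeing the data. The mitochondrially encoded genes, 7 of the 10 long noncoding RNAs listed, SNORD3A and USP36 could not be named from the tables and were not analysed here, nor were sequences of the Cas9 and fluorescent protein transgenes. Some genes that this rule takes, and 1 list with a median ratio, are not reported here.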

Results

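Gene and transcript levels were measured in a recombinant line of U2OS, a human osteosarcoma cell line. The line carries a fluorescent reporter of the passage from G1 to S phase and also makes Cas9, a nuclease, under control of a CAG promoter. In this reporter a green fluorescent protein is fused to the C-terminal localisation domain of DNA helicase B (HELB). Both libraries came from untreated cells and form 1 group of 2 replicates, so the design holds no contrast between conditions. The labels do not say whether the replicates were separate cultures, so the spread between them may be technical. Levels are FPKM as deposited, given as mean ± SD with n = 2. Coverage per FPKM had a median of 5.78 in replicate 1 and 5.57 in replicate 2, and the absolute depth is unknown.

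Ribosomal protein genes and GAPDH were among the 15 genes of highest mean FPKM. GAPDH, a glycolytic enzyme, stood at 4936 ± 1261. The ribosomal protein genes RPLP1 (4073 ± 1217), RPL41 (3911 ± 1093), RPS27 (3846 ± 629) and RPS29 (3791 ± 379) followed, with RPS2, RPL8, RPLP0, RPS24, RPS18 and RPL38 also in this group. The cytoskeletal gene ACTB was at 3782 ± 281, the translation elongation factor EEF1A1 at 2820 ± 437 and the galectin LGALS1 at 2719 ± 966. The highest named gene was LOC101927337, at 5988 in replicate 1 and 12259 in replicate 2, whose longest listed transcript has 103 bases (GRCh38 chromosome 17, 53088581 to 53105822). Of 29098 genes, 12068 were detected in replicate 1 and 12125 in replicate 2, and 11776 in both. By GENCODE type 11223 of the 11776 were protein-coding. Among the 11776 genes, 5293 had a mean FPKM of 1 to 10 and 5789 of 10 to 100. The 100 highest genes held 33.3% of the summed FPKM of named genes in replicate 1 and 31.4% in replicate 2.

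The machinery of the G1 to S transition was expressed almost throughout: 21 of 22 listed genes were detected in both libraries. Among the D-type cyclins, which activate CDK4 and CDK6, CCND1 stood at 71.8 ± 1.64 and CCND2 at 63.8 ± 3.58, and CCND3 at 18.1 ± 5.33. CDK4 was at 113 ± 20.5 and CDK6 at 51.9 ± 13.7, and CDK4 was above CDK6 in each library. CCNE1, the cyclin partner of CDK2 at S-phase entry, was at 38.7 ± 0.246, CCNE2 at 8.12 ± 1.16 and CDK2 at 53.5 ± 2.52. The pocket proteins were at 18.6 ± 2.84 for RB1, 11.7 ± 0.651 for RBL1 and 20.4 ± 1.98 for RBL2. Among the E2F transcription factors, E2F4 was at 43.0 ± 5.98 and E2F1 at 19.9 ± 2.77, with E2F3 at 10.1 ± 0.488 and E2F2 at 4.96 ± 0.245. Their partners TFDP1 and TFDP2 were at 49.6 ± 4.32 and 5.92 ± 0.348. MYC was at 64.9 ± 2.66, SKP2 at 34.8 ± 5.71, FBXW7 at 12.5 ± 1.79 and CDC25A at 12.3 ± 0.862. E2F5 was listed at 0 in both libraries, and its span overlaps RBIS, an expressed gene.

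All 32 listed genes of replication origins and S phase were detected in both libraries. The highest were MCM7, a subunit of the replicative helicase, at 248 ± 35.4, the thymidylate synthase TYMS at 227 ± 30.3, the sliding clamp PCNA at 207 ± 4.11 and the ribonucleotide reductase subunit RRM2 at 172 ± 0.610. All 32 listed genes of G2 and mitosis were also detected, led by CDC20 (198 ± 47.6) and UBE2C (195 ± 31.5), which act with the anaphase-promoting complex. The mitotic cyclin CCNB1 was at 150 ± 13.04 and ANLN, a cytokinesis gene, at 149 ± 14.4. A further list held genes of ubiquitin ligases that time the cycle and their partners (anaphase-promoting complex, SCF and the CUL4A ligase with DDB1). Of these, 22 of 24 genes were detected, with CKS2 at 183 ± 37.5, CKS1B at 151 ± 29.3, DDB1 at 119 ± 11.0 and SKP1 at 62.8 ± 0.276. ANAPC10, which overlaps the expressed gene ABCE1, and ANAPC15 were listed at 0 in both libraries.

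**Figure D1:**
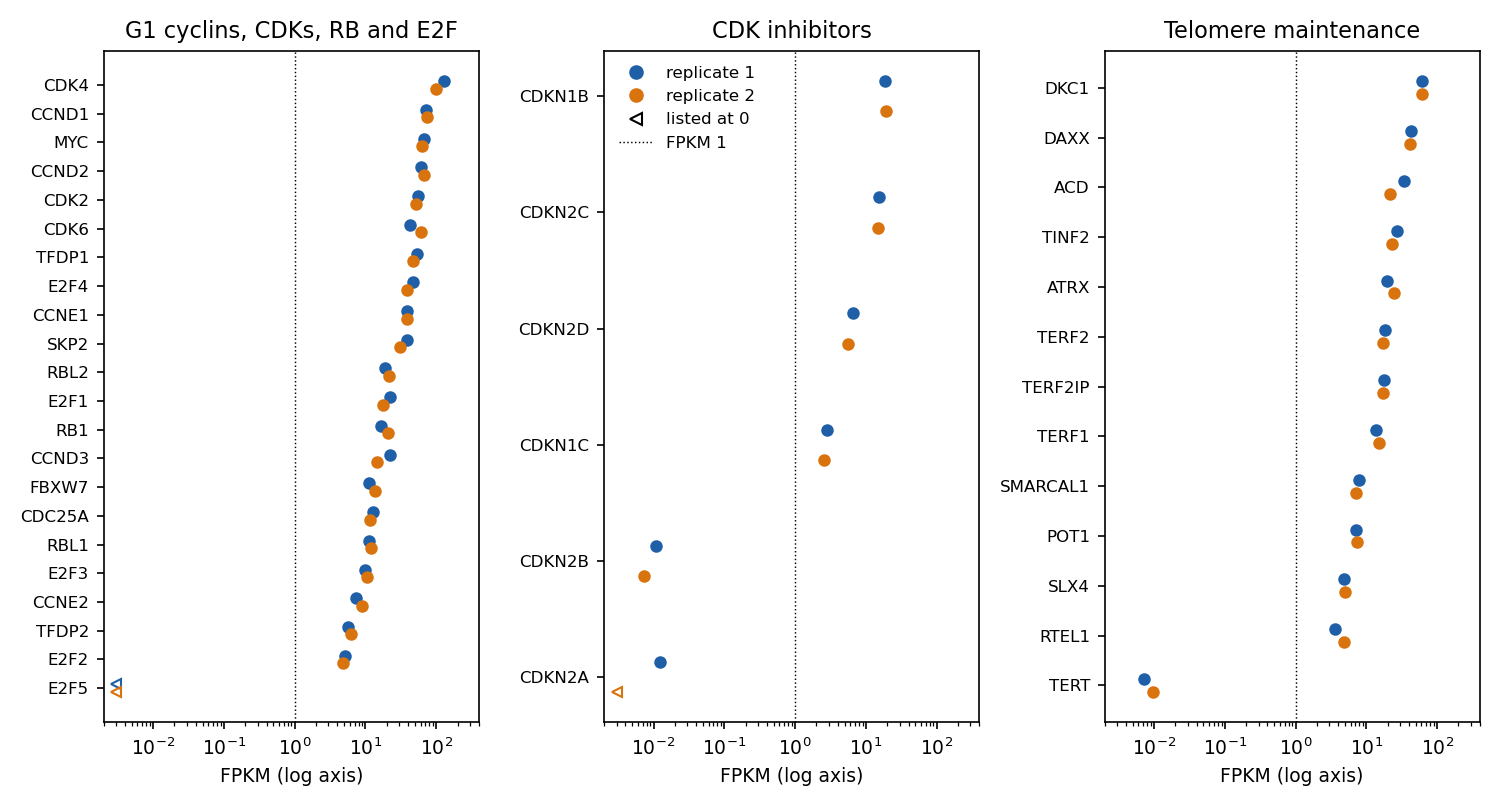
FPKM on a log axis of each measured gene of the G1 machinery, the CDK inhibitors and telomere maintenance, with 1 point for each replicate library and open triangles at the left edge for values listed at 0. CDKN2A, CDKN2B and TERT lie under FPKM 0.02, E2F5 is listed at 0, and the other genes lie right of the dotted line at FPKM 1.

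The INK4 inhibitors of CDK4 and CDK6 differed widely in level. CDKN2C was at 14.9 ± 0.437 and CDKN2D at 6.07 ± 0.570. CDKN2A (GRCh38 chromosome 9, 21967752 to 21994491) was at 0.0125 in replicate 1 and at 0 in replicate 2, and CDKN2B was at 0.00909 ± 0.00234. Of the CIP/KIP inhibitors, CDKN1B was at 19.05 ± 0.338 and CDKN1C at 2.70 ± 0.176. In all, 4 of the 6 measured inhibitors were detected. CDKN1A was left out because its estimate failed in replicate 2, and its deposited values were 159 in replicate 1 and 120 in replicate 2.

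The apoptosis gene BAX was at 270 ± 80.7, the ferredoxin reductase FDXR at 133 ± 41.3, the damage recognition gene DDB2 at 98.1 ± 11.2 and the ubiquitin ligase MDM2 at 94.7 ± 14.9. The phosphatase PPM1D was at 20.5 ± 0.994. For telomere maintenance, 12 of 13 genes were detected. The telomerase reverse transcriptase TERT was at 0.00849 ± 0.00179, while DKC1, a telomerase-associated protein, was at 60.8 ± 0.576. The chromatin remodelling partners ATRX and DAXX were at 22.2 ± 3.81 and 41.9 ± 1.18. The shelterin genes ranged from POT1 (7.17 ± 0.180) through TERF1 (14.5 ± 1.00), TERF2IP (17.6 ± 0.343), TERF2 (17.7 ± 0.553) and TINF2 (25.04 ± 3.03) to ACD (27.6 ± 8.78). SMARCAL1 was at 7.46 ± 0.569, SLX4 at 4.94 ± 0.0893 and RTEL1 at 4.23 ± 0.865.

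DNA repair genes that act on nuclease-made breaks were expressed. All 17 end-joining genes were detected, with the Ku subunits XRCC6 at 333 ± 8.30 and XRCC5 at 155 ± 4.16 above the other members in each library. FEN1 was at 78.8 ± 1.03, the kinase PRKDC at 67.8 ± 17.1 and PARP1 at 62.4 ± 2.31. PAXX was at 23.8 ± 11.0, XRCC1 at 17.4 ± 1.28, TP53BP1 at 16.1 ± 1.72, XRCC4 at 14.8 ± 0.798, LIG3 at 14.2 ± 0.617 and RIF1 at 11.998 ± 2.67. POLL was at 9.44 ± 1.68, NHEJ1 at 8.43 ± 0.537, DCLRE1C at 7.78 ± 0.645, POLQ at 5.56 ± 1.18, LIG4 at 4.31 ± 0.799 and POLM at 3.83 ± 0.694. For homologous recombination 25 of 26 genes were detected, led by RAD51C (48.7 ± 7.04), RBBP8 (40.7 ± 3.18), RPA2 (36.0 ± 0.00955) and RAD51AP1 (33.7 ± 1.79). The reference transcripts of RAD51D were at 0 in both libraries, while assembled transcripts of its locus, which also holds another gene, summed to 4.83 in replicate 1 and 5.52 in replicate 2.

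Of the genes for DNA sensing and interferon responses, 10 of 20 were detected in both libraries. Among them were IRF3 (20.2 ± 0.912), ISG15 (14.0 ± 3.39) and TBK1 (12.4 ± 1.51). Other members of this list lay under FPKM 1 in both, from IFIT1 (0.975 ± 0.0303), IFIT3 (0.891 ± 0.0249) and OASL (0.757 ± 0.0764) to OAS1 (0.415 ± 0.0671), MX1 (0.293 ± 0.0183), IFIT2 (0.207 ± 0.00547), IRF7 (0.0640 ± 0.0135) and RSAD2 (0.00997 ± 0.00829). IFNB1 and AIM2 were listed at 0 in both. With a lower confidence bound above 0 as the criterion, 16 members counted as detected.

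All 31 proteasome genes were detected in both libraries, the highest being the core subunits PSMB4 (203 ± 49.3), PSMB3 (194 ± 57.7) and PSMB1 (191 ± 19.2) and the ATPase PSMC5 (184 ± 14.7). Of 54 deubiquitinases 49 were detected, with USP22 at 124 ± 2.54, USP5 at 73.6 ± 9.43, USP10 at 48.2 ± 2.50 and USP1 at 43.8 ± 6.65. USP18 (0.938 ± 0.0163), USP44 (0.0381 ± 0.00156) and USP29 (0.00777 ± 0.00534) were under FPKM 1 in both, and UCHL1 was at 0 in replicate 1 and at 0.0295 in replicate 2.

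Markers of the bone lineage were partly expressed, with 7 of 16 detected in both libraries. SPARC, a matrix protein, stood at 304 ± 11.0 and the collagen gene COL1A1 at 75.9 ± 9.46, but COL1A2, which encodes the partner chain, was at 0.0744 ± 0.00922. MSX2 was at 4.12 ± 0.211, RUNX2 at 2.64 ± 0.554, ALPL at 2.09 ± 0.458 and SPP1 at 1.84 ± 0.232. SP7, DLX5, PTH1R, PHEX and DMP1 were under FPKM 0.11 in both, OMD was at 0 and 0.00581, and IBSP and BGLAP were listed at 0. The span of BGLAP overlaps the expressed gene PAQR6. At FPKM 5 or more only 2 of the 16 counted as detected.

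Of the mesenchymal markers 15 of 20 were detected, with LGALS1 (2719 ± 966), the intermediate filament VIM (909 ± 132), fibronectin FN1 (90.1 ± 27.1) and THY1 (66.9 ± 9.84) highest. NT5E (0.0198 ± 0.00306), ZEB2 (0.0705 ± 0.0231) and TWIST2 (0.892 ± 0.0726) were under FPKM 1 in both, and TWIST1 was at 0 in replicate 1 and 0.844 in replicate 2. Of 14 measured epithelial markers 5 were detected, the highest of these 14 being EPCAM (12.9 ± 1.29), CLDN4 (9.78 ± 2.94), KRT7 (4.98 ± 2.36) and KRT14 (3.52 ± 1.48). The keratins KRT8 and KRT18 were left out of this count and ranking because of a failed status, not for a low value. With entries of any status, which adds both, 7 epithelial markers were detected. KRT5, KRT19, ESRP1 and ELF3 were under FPKM 1 in both libraries, OVOL1 was at 0.0109 and 0, and CLDN3, CLDN7, ESRP2 and GRHL2 were listed at 0 in both, CLDN7 overlapping the expressed gene ELP5 and ESRP2 overlapping NFATC3. Of 11 chondrocyte markers 3 were detected, with SOX9 at 33.3 ± 2.73, COL9A2 at 8.21 ± 0.203 and MATN3 at 6.13 ± 0.497, and COL2A1 was at 0.0242 ± 0.00541. SOX5, ACAN, COL9A1, COL10A1, COL11A2 and CNMD were also under FPKM 1 in both libraries. At FPKM 0.5 or more, 6 of the 11 counted.

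Markers of other lineages were mostly under FPKM 1. Of 14 haematopoietic markers 1 was detected, the lysosomal gene CD68 at 2.93 ± 0.858, and PTPRC was at 0.155 ± 0.0310. Of 9 endothelial markers ERG alone was detected, at 1.47 ± 0.311. Of 11 muscle and fat markers CFD (4.38 ± 2.45) and LPL (1.44 ± 0.0833) were detected. Of 12 liver and neural markers 5 were detected, with the neurofilament gene NEFL at 24.7 ± 0.428, RBFOX3 at 9.21 ± 2.25, MAP2 at 2.38 ± 0.115 and AFP at 1.40 ± 0.158, while ALB was at 0.0384 and 0 and SOX10 at 0.0152 ± 0.0146.

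Among housekeeping and stress programmes, all 54 ribosomal protein genes, all 10 measured heat shock genes and all 18 genes of cholesterol synthesis were detected. HSPB1 led the heat shock genes (878 ± 314), before HSPA8 (740 ± 38.9), HSP90AA1 (543 ± 0.101) and HSPD1 (328 ± 35.1). Among the cholesterol genes, FDPS was at 61.6 ± 7.48, FDFT1 at 59.2 ± 6.73 and SREBF2 at 56.5 ± 5.12. For glycolysis and hypoxia 20 of 22 were detected, with ENO1 (1570 ± 419), PKM (1329 ± 328) and LDHA (745 ± 111) after GAPDH, and CA9 and ANKRD37 were listed at 0, ANKRD37 overlapping the expressed gene UFSP2. For the integrated stress response and amino acid synthesis 15 of 16 were detected, with ATF4 at 314 ± 59.6, HSPA5 at 185 ± 4.97, SLC7A5 at 178 ± 32.8 and ASNS at 122 ± 17.0. DDIT3 was listed at 0 in both, and its span overlaps the expressed gene MARS1.

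Of 21 replication-dependent histone genes 15 were detected, led by H2BC12 (161 ± 3.76), H1-2 (147 ± 4.10), H2AC6 (43.6 ± 7.94) and H2BC4 (17.8 ± 0.330), and the near-identical copies within this family may share reads. Some histone genes are also known to make transcripts with a poly(A) tail. Of 12 measured noncoding RNAs without a poly(A) tail 7 were detected, with RN7SK at 126 ± 25.8, RN7SL1 at 97.1 ± 15.3, RMRP at 58.9 ± 36.6 and RN7SL2 at 51.7 ± 1.46. Of 3 long noncoding RNAs that could be named, MALAT1 and NEAT1 were detected and LINC-PINT was at 0.396 ± 0.121. Of 16 immediate early genes 13 were detected, with CCN1 at 269 ± 35.6 and CCN2 at 241 ± 74.4 highest.

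HELB, whose C-terminal domain is part of the reporter, was at 18.9 ± 0.129 (GRCh38 chromosome 12, 66302555 to 66343643). Reads from the HELB part of the reporter and from the HELB gene cannot be told apart in these values.

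The replicates were next compared over 12417 genes at FPKM 1 or more in at least 1 library. Of 14 immediate early genes 13 were higher in replicate 2, with a list median of 0.38 (log2), above the central 95% of random lists (-0.29 to 0.05). FOS, an immediate early transcription factor, was at 8.40 in replicate 1 and 55.1 in replicate 2 (GRCh38 chromosome 14, 75278778 to 75282234). EGR1 was at 29.9 and 89.6, and CCN2 at 189 and 294. The nuclear RNAs MALAT1 (18.9 and 80.4) and NEAT1 (56.7 and 105) were also higher in replicate 2. Of 15 integrated stress genes 13 were higher in replicate 1 (median -0.38, random range -0.30 to 0.05), with ATF4 at 356 in replicate 1 and 272 in replicate 2. Of 7 noncoding RNAs without a poly(A) tail 5 were higher in replicate 1 (median -0.42, random range -0.39 to 0.12), with RMRP at 84.8 and 33.0.

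**Figure D2:**
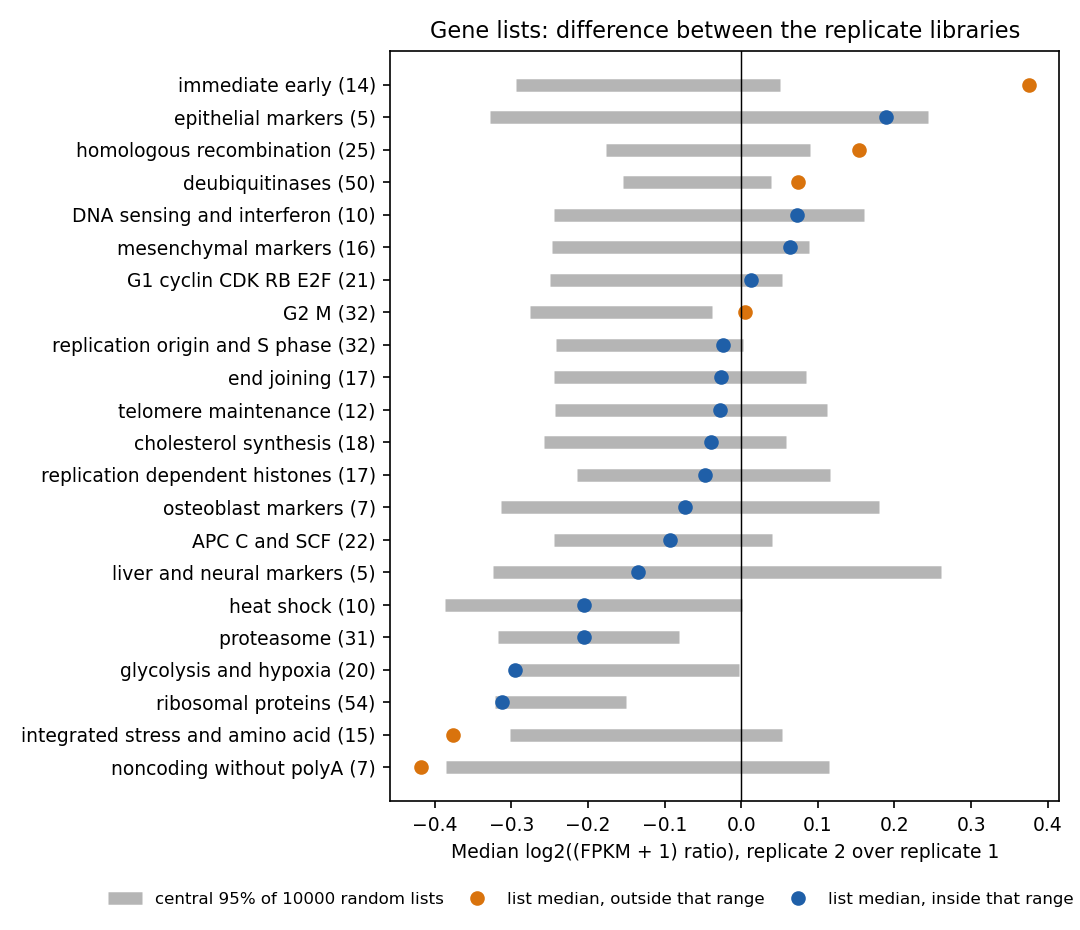
Median log2 ratio of (FPKM + 1), replicate 2 over replicate 1, of 22 lists with 5 or more members (number in brackets), over the central 95% of 10000 random lists matched on mean expression. Immediate early genes lie highest at 0.38 and noncoding RNAs without a poly(A) tail lowest at -0.42.

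Of 23 lists with a value, 7 lay outside the central 95%, 5 above and 2 below, against 1.15 expected for lists of genes drawn independently. Random lists were matched on mean expression only, and members of a list can share other features, so 1.15 is not a chance count for these lists. Homologous recombination (median 0.15), deubiquitinases (0.07) and G2 and mitosis (0.01) were also above. With FPKM rescaled to a common sum the median of G2 and mitosis was -0.076, still above the central 95% of its random lists. The ratios varied with transcript length: with genes split into 4 bins of equal size, the median ratio was -0.24 in the bin of shortest transcripts (median length 1294 bases) and 0.12 in the bin of longest (5871 bases). Across genes, which are not independent replicates, the ratio had a Spearman rho of 0.49 with transcript length and -0.59 with GC content. With that trend removed, homologous recombination, deubiquitinases and G2 and mitosis lay inside the central 95%, while end joining, epithelial markers, heat shock, glycolysis and hypoxia, and histones, which had been inside, lay outside. Integrated stress genes stayed outside, with a median of -0.23. Before that step 16 lists were inside the range, with medians from -0.31 (ribosomal proteins) to 0.19 (epithelial markers), and glycolysis and hypoxia was at -0.30.

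Of the 12417 genes 147 differed between the libraries, 60 higher in replicate 2 and 87 higher in replicate 1. Only the 12000 genes with confidence bounds could be counted as differing. ARPC1B (123 and 0), AIMP2 (43.5 and 0), CTU2 (26.9 and 0), NTMT1 (22.4 and 0), LLGL1 (22.4 and 0), C19orf47 (13.2 and 0), SGO1-AS1 (10.7 and 0) and GNPDA2 (10.1 and 0) were listed at 0 in replicate 2. LOC101926982 (56.9 and 0.236) and LOC101929521 (11.97 and 0.282) were low there. GLT8D1 (0 and 19.7), MTIF3 (0 and 10.9) and the small nucleolar RNAs SNORD47 (0 and 137) and SNORD97 (0 and 12.4) were listed at 0 in replicate 1. The other genes of largest ratio toward replicate 2 were FOS, SNORA33 (5.68 and 37.4), LOC102723755 (1.11 and 11.1), ZNF595 (3.75 and 21.3), ITGAE (1.75 and 11.1) and SNORA62 (22.3 and 97.2). Of the genes named here as listed at 0, all but GNPDA2 and SNORD47 overlap a named gene at FPKM 1 or more. Genes that could not be named were not part of this check, so these exceptions may overlap such a gene. The count was 88 without genes at 0 in either library, 95 without overlapping genes, and 248 with a pseudocount of 0.1.

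**Figure D3:**
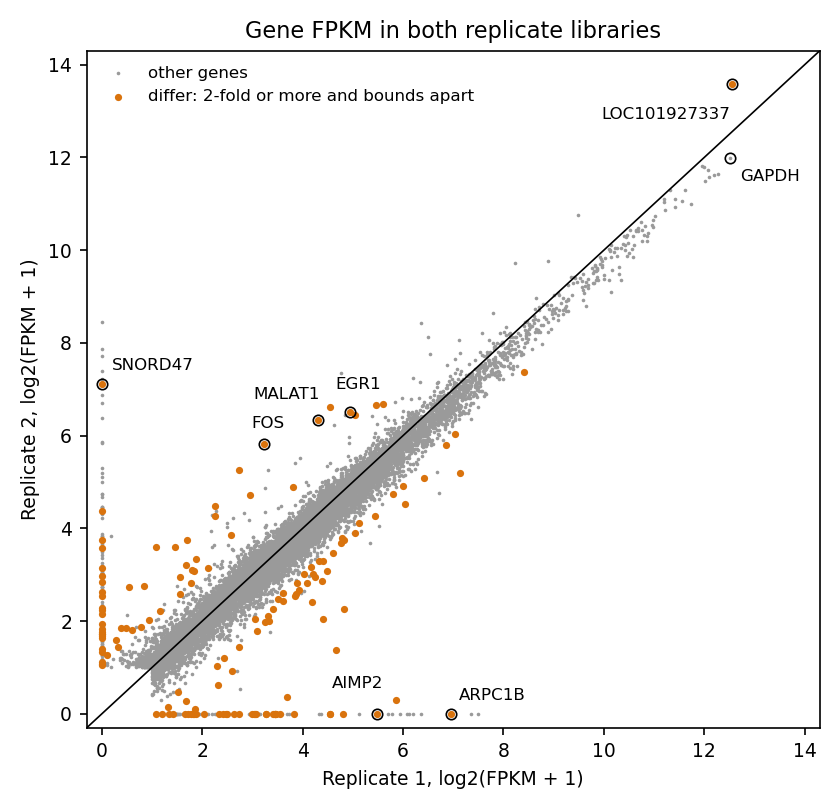
Each point is a gene at FPKM 1 or more in at least 1 library, with log2(FPKM + 1) in replicate 1 on the horizontal and in replicate 2 on the vertical axis; the line marks equal values and orange points are the 147 differing genes. Genes on either axis are listed at 0 in 1 library, and FOS, EGR1 and MALAT1 lie above the line.

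Across those genes the libraries had a Pearson r of 0.951 and a Spearman rho of 0.959, and the SD of the log2 ratio was 0.56, with an interquartile range of -0.25 to 0.13. Among genes at mean FPKM of 5 or more, the SD was 0.56 and the SD estimated from the median absolute deviation, which outlying genes affect less, was 0.28. Among 8837 genes at mean FPKM of 5 or more, 93.3% lay within 1.5-fold. The deposited confidence bounds did not overlap for 6748 of 12000 genes with bounds (56.2%), so these bounds were narrower than the spread between libraries.

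Of the reference transcripts 17319 were detected in replicate 1 and 17071 in replicate 2, and 15002 in both. Of 8646 genes with several transcripts, 7320 (84.7%, 95% Wilson interval 83.9% to 85.4%, over genes) had the same leading reference transcript in both libraries. That transcript held a median of 80.0% of its gene's reference FPKM in replicate 1 and 80.8% in replicate 2. Assembled transcripts, which cannot be matched between libraries, were not part of this comparison. The interval counts genes as independent units, which they are not. CDK2 (NM_001798.3 of 2 transcripts, 55.3 and 51.8), CCNE1 (XM_006723457.1 of 3, 38.5 and 38.8) and ATRX (XM_006724667.1 of 10, 19.5 and 24.9) each had all of their FPKM on 1 transcript in both libraries. These values do not show whether every exon of a transcript was covered, so they do not show that an intact mRNA is made. RB1 (NM_000321.2, 16.5 and 20.6), CDK4 (NM_000075.3, 128 and 98.6) and PPM1D (NM_003620.3, 19.8 and 21.2) have 1 reference transcript each. MDM2 was spread over 3 transcripts, the leading one (XM_006719399.1) holding 41.4% and 45.8%. CCND1 had 1 transcript in replicate 1, and in replicate 2 NM_053056.2 held 73.5% and XM_006718653.1 held 26.5%. HELB was wholly on NM_033647.3 in replicate 1 (19.01), but in replicate 2 that transcript held 19.5% (3.66), and 2 transcripts assembled by Cufflinks held 68.7% (12.9) and 11.9% (2.23). For CDKN1A, NM_001220777.1 led in replicate 1 (102, 64.3%), and all its transcripts had a failed status in replicate 2. The only transcript of CDKN2A above 0 was NM_000077.4, at 0.0125 in replicate 1.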

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

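These results were picked because a signal appeared in entries that none of the comparisons used. None of the tests in this part was chosen after its result was seen.

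Loci made only of assembled transcripts, with no gene name, held 49.6% of the summed FPKM in replicate 1 and 55.9% in replicate 2 (24145 and 34509 loci). Short length inflating FPKM is a candidate explanation: the loci held at most 8.33% of the covered bases in either library, and those under 200 bases held 92.2% and 91.1% of the loci's FPKM. For the larger number in replicate 2, unspliced or nuclear RNA may contribute, since loci inside expressed genes were 1.68 times as many as in replicate 1 (1.63 to 1.73, counting error only), against 1.33 times (1.31 to 1.36) outside named genes, but the factor inside genes under FPKM 0.1 lay between these, at 1.48 (1.36 to 1.61), so expressed genes need not account for all of the increase. Genomic DNA cannot be told apart from RNA here. In replicate 2 the density of loci in genes under FPKM 0.1 was 0.331 of that in expressed genes, between the bounds set for either outcome. In replicate 1 it was 0.376. The design has 1 group, so no biological explanation was tested.

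The highest FPKM in either transcript table belonged to an 89-base reference transcript with no symbol (GRCh38 chromosome 1, 632325 to 632413), at 28431.7 in replicate 1 and 50315.8 in replicate 2. Entries on the mitochondrial chromosome (25) summed to FPKM 568.6 in replicate 1, and replicate 2 had 0 such entries.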

How the results depend on the processing

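No paired analysis was possible because the series has 1 group. Reference transcripts only, genes at 0 or overlapping genes left out, and removal of the length and GC trend were chosen after seeing the data. Of the recounts of list members, 224 stayed within 1.5 times the reported count and 16 did not. All 8 recounts of detected genes stayed within that wide band, but they varied around the reported 11776. They ranged from 8464 at FPKM 5 or more to 15910 with a lower confidence bound above 0. With reference transcripts only, 10017 genes were detected. Of the recomputed list shifts, 168 kept their side of the central 95%, though 13 of these medians changed sign, 4 moved inside it, 6 moved outside, and 2 moved outside in the opposite direction. The noncoding RNAs without a poly(A) tail had too few members with both a length and a GC value for removal of the trend. Without replicate 1 or replicate 2, 12068 to 12125 genes and 17071 to 17319 transcripts were detected. At FPKM 5 or more, 8751 transcripts were detected in both libraries, and 2 osteoblast, 2 epithelial, 0 haematopoietic, 0 endothelial, 0 muscle and fat, 2 liver and neural and 9 histone members. At FPKM 0.5 or more, 6 chondrocyte and 2 endothelial members were detected. With a lower confidence bound above 0, these were 16 DNA sensing, 8 epithelial, 9 chondrocyte, 6 haematopoietic, 7 endothelial, 6 muscle and fat and 9 liver and neural members. These counts follow from the level of the minimum or from the criterion used in its place. Pearson r between the libraries was 0.8974 with a pseudocount of 0.1, 0.9797 with no minimum and 0.9194 at FPKM 5 or more. Differing genes numbered 248 with a pseudocount of 0.1, 88 without genes at 0 and 95 without overlapping genes. With the length and GC trend removed, the medians of G2 and mitosis (-0.054), deubiquitinases (-0.039), homologous recombination (-0.027) and 1 other list (-0.021) lay inside the central 95%, those of end joining (0.028), epithelial markers (0.247), heat shock (-0.202) and glycolysis and hypoxia (-0.198) outside, and histones turned to 0.254, above it. With no minimum, ribosomal proteins (-0.312) and glycolysis and hypoxia (-0.296) lay outside. With entries of any status, which adds KRT8 and KRT18, epithelial markers turned to -0.382. Agreement of the leading transcript was 89.12% at gene FPKM of 10 or more. Where no cause is given, the cause was not tested. The unknown absolute depth limits what can be said of genes near 0.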

Other observations

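Cancer-testis genes, which are normally restricted to germ cells, were among the expressed genes. Of 17 measured, 8 were detected in both libraries. MAGEA4 stood at 157 ± 25.7, PRAME at 106 ± 16.9, MAGEA1 at 73.6 ± 5.85 and MAGEB2 at 67.0 ± 8.37, and MAGEA3 and MAGEA6 may share reads as near-identical copies. CTAG1B and SSX2 were listed at 0 in both libraries, and a listed 0 can be a failed estimate.

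Of 32 receptor tyrosine kinases 20 were detected in both libraries, with AXL at 140 ± 21.6, EPHA2 at 58.7 ± 6.29, EPHB4 at 36.3 ± 5.00 and DDR1 at 25.2 ± 2.08. EGFR was at 6.50 ± 1.26, and in each library all of that value lay on transcripts assembled in its locus. KIT was at 0.00265 in replicate 1 and 0 in replicate 2. Of 22 circadian clock genes 19 were detected, among them CSNK1E (68.8 ± 2.61), CSNK1D (52.3 ± 12.1), BHLHE40 (35.7 ± 0.171) and NR1D2 (31.3 ± 4.38). Of 28 nuclear receptors 14 were detected, led by NR1H2 (22.9 ± 4.94), RARA (20.7 ± 2.29) and PPARG (18.5 ± 2.61), and ESR1 was at 0.0322 ± 0.00253. RARB, NR1H3 and ESRRA were listed at 0 in both libraries, and each overlaps an expressed gene (TOP2B, ACP2 and TRMT112). Of 38 HOX genes 21 were detected, led by HOXB9 (17.8 ± 1.66), HOXB7 (16.5 ± 1.15) and HOXC13 (9.55 ± 1.48), and of those listed at 0 in both libraries HOXC5 and HOXD1 overlap an expressed gene. Genes in both paragraphs were picked after their values were seen. All 24 other short-lived mRNAs were detected in both libraries, and their median ratio was 0.00.

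The tests of overlap and of short transcripts were chosen only after their results were seen. The short-transcript test replaced a test of read coverage, whose outcome FPKM of 5 or more fixes in advance. Overlap was looked for among named genes only. Of 120 genes listed at 0 in 1 library and at FPKM 5 or more in the other, 69 (57.5%) overlapped another expressed gene, against 971 of 8460 genes at FPKM 5 or more in both (11.5%, Fisher's exact p = 4.3e-33, two-sided). Of the 120, 84 (70%) had no named transcript of 200 bases or more, against 84 of 8460 (0.993%, Fisher's exact p = 1.7e-124). Short genes of equal length could share 1 FPKM value, such as 5.68 for MIR608 and RNU5D-1, both of 100 bases. Few fragments may thus bring a short gene to FPKM 5, so the choice of genes favours short ones in advance. The p-value of the short-transcript test therefore lends no further support. Among the 36 longer genes, 23 overlapped (63.9% against 11.2%, Fisher's exact p = 9.0e-14). Of 52 overlapping genes with a known strand for both genes, 18 had an overlapping gene on the opposite strand. The Fisher tests count genes as independent units, which they are not. An assignment of reads to the overlapping gene and few fragments on short transcripts are candidate explanations, and no biological explanation was tested.

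Immediate early genes were higher in replicate 2, and a trend with gene length and GC content as the whole cause is argued against, since the list stayed at percentile 100 of random lists (median 0.54) after its removal. FOS, FOSB and EGR1 were not the only members involved: without them the median of the other 11 was 0.30, also at percentile 100. FOSB, at 0.461 in replicate 1 and 5.69 in replicate 2, was chosen after its values were seen. A higher share of short-lived or nuclear RNA in replicate 2 may contribute and cannot be told apart, since the other short-lived mRNAs lay at percentile 85.2. The design has 1 group, so no biological explanation was tested.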
